A study of Auxenochlorella pyrenoidosa with 12 samples.

How the data were processed

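Transcript levels were measured by RNA sequencing of 12 libraries of Chlorella pyrenoidosa, prepared with an Illumina TruSeq RNA kit from total RNA of whole cells, per the labels' protocols. The series also describes lower PMS concentrations of the chronic exposure, which are not analysed here. Groups came from the library titles, read as dose, day and replicate, and the sampling days match those of the series' design text. Treated groups received 8.49 mg/L PMS and were sampled on day 0 and every 3 days after it, to day 12. The control libraries carry a label that can be read as dose 0 or as day 0, so no day was given to the control. Each of the 6 groups held 2 libraries, while the design text speaks of 3 or more repeats of each exposure group without saying which measurements they refer to. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

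The deposited table holds FPKM values computed by the authors, 1 column per library, for 30814 contigs, and every column of it belongs to an analysed library. Row names are those that the Trinity assembler gives to contigs, followed by an appended number from 1 to 4 whose meaning is not given in the sources used here. Each combination of Trinity gene and appended number occurs once, so the table lists 1 contig per such unit. The settings of the assembly, the program that estimated abundance, the read filters and any annotation are not given in the sources used here. No reference genome or annotation was used, and the IDs were matched against 26 lists of genes fixed in advance (such as antioxidant enzymes, photosystems and ribosomes) with 0 matches, so no gene list or annotation term could be tested. FPKM is a share of each library, so a change in a few abundant contigs shifts all others. The most abundant contig alone took 4.69% of the total FPKM in a control library and 10.9% in a day 6 library. Values for contigs of the same gene family can also share fragments, and how these were divided is not given in the sources used here.

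Depth in reads is unknown. Low FPKM values were checked for steps of a single fragment by comparing each library with control library 1 over contigs between 0.01 and 1 FPKM. In 7 libraries the ratios clustered at whole-number steps at least 2 times above background, with a relative depth of 0.946 to 1.07. The check cannot tell a depth from 1 that is 2 times higher or lower, so it does not show that these libraries had similar depths. The other libraries gave no clear step, so no fragment counts were recovered and no counting interval is given. Libraries of a group were compared for duplication, and no pair shared a single identical value above 0.

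Values were analysed as log2(FPKM + 1) for contigs with a mean of at least 1 FPKM over the 12 libraries, which kept 17653 and left out 13161. Contrasts were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with all 12 libraries in a single fit of group means and 6 residual degrees of freedom. The 9 contrasts were each treated day against the control and each treated day against the previous sampling day, each with Benjamini-Hochberg adjustment and a threshold of 0.05. A moderated F test covered the 5 treated days. Fold changes are on the log2(FPKM + 1) scale unless FPKM is named, and this scale understates the change of low contigs. Log2 ratios of library 1 to library 2 of a group were instead computed per contig on log2(FPKM + 0.1). With 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333, so single values of a pair of groups were not tested that way. The number of contigs below 0.01 FPKM was tested over all 6 groups, by the squared spread within groups over all ways to pair the 12 libraries. Principal components and correlations were computed on the same 17653 contigs. Python 3.11.15 was used for library summaries and figures.

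The test was tried on simulated data built from the means and the spread of the 17653 contigs, with 200 contigs changed on day 0. For day 0 against the control, 45 of 100 contigs changed by 1 on the log2 scale and 91 of 100 changed by 2 were called, with 1 false call. A change of 1 on the log2 scale was thus often missed in this simulation. Only 200 of the 17653 contigs were changed in it, against 3303 called in the real contrast, so its adjusted threshold was stricter. The share of changes missed in the real contrasts is not shown by it. Numbers of contigs called in several contrasts were set beside the number that independent lists would share. In 20 simulated draws without any change these numbers were 0, which the adjusted threshold all but fixes, so they are no measure of the overlap between lists that hold real changes.

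Since the table has no gene names, at most 2 IDs that rose and 2 that fell are named, by a rule of largest change among called contigs whose treated libraries lay on the same side of both control libraries. They were taken from day 0 against the control, and the choice of that contrast was made after the data were available. The rule, the tests and the alternatives were written before the data were examined, except where stated. The alternatives were a pseudocount of 0.1, no low-value filter, a minimum mean of 5 FPKM, libraries rescaled by the median ratio to the geometric mean of all libraries over contigs above 0 in all of them, the replicate number as a block, a minimum change of 2-fold, a fit of the compared groups alone, and leaving out each library in turn. A fit without the early-unmeasured contigs, and leaving out day 3 library 1 from contrasts without day 3, were added after seeing the data.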

Results

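The study exposed Chlorella pyrenoidosa (also Auxenochlorella pyrenoidosa), a unicellular freshwater green alga, to potassium peroxymonosulfate (PMS), an oxidant used in water treatment and disinfection. Cultures received 8.49 mg/L, which is 0.5 of the median effective concentration (EC50) of the acute test. RNA of whole cells was sequenced in 12 libraries. Treated cultures were sampled on day 0 and then every 3 days to day 12, with 2 libraries per day, and the control without PMS had 2 libraries. The day of the control is not stated unambiguously, and no control of the later days was analysed here, so a difference between a later day and the control holds the exposure and the age of the culture together. Expression was given as FPKM, fragment numbers scaled to transcript length and to the total of the library, for 30814 contigs of a de novo transcriptome assembly. The table pairs no contig with a gene name, so contigs are described below by how they behaved across the libraries. Total FPKM per library ranged from 487140 to 603105, and the number of reads behind each library is unknown.

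The day 0 libraries lay close to the control, and the largest step in the transcriptome fell between day 0 and day 3. Over the 17653 contigs with a mean of at least 1 FPKM, the Pearson correlation of log2(FPKM + 1) between a control and a day 0 library was 0.932 to 0.955. Between day 0 and day 3 libraries it was 0.661 to 0.759, between control and day 3 libraries 0.663 to 0.775, and between control and day 12 libraries 0.581 to 0.607. Neighbouring late days resembled each other, with 0.834 to 0.864 between days 3 and 6, 0.924 to 0.964 between days 6 and 9 and 0.933 to 0.964 between days 9 and 12. Within groups the correlation was 0.988 for the control pair, 0.979 for day 0, 0.931 for day 3, 0.977 for day 6, 0.955 for day 9 and 0.979 for day 12. Above the value of the day 9 pair lay day 9 library 1 with the day 6 libraries, at 0.963 and 0.964. So did day 9 library 2 with the day 12 libraries, at 0.964 and 0.961. The other pairs of a day 9 library with a day 6 or day 12 library lay below it. These correlations run across contigs, which are not independent replicates. The first principal component held 65.2% of the variance and placed control and day 0 at one end and days 6 to 12 at the other. The second, with 16.8%, set the day 3 libraries apart from all others. The day 3 libraries also lay further from each other on the first component than any other pair of one group, at 39.1 and 5.25.

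**Figure D1:**
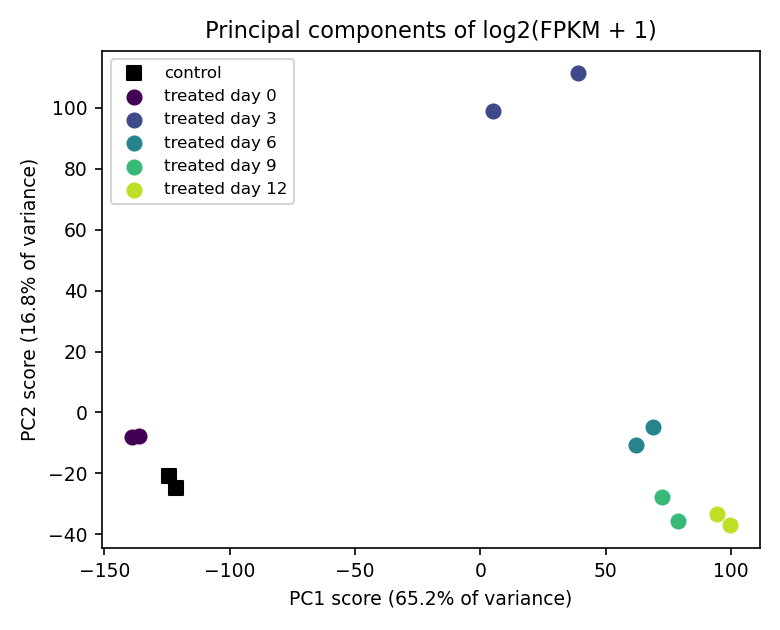
Scores of the 12 libraries on the first (x axis, 65.2% of the variance) and second (y axis, 16.8%) principal component of log2(FPKM + 1) over 17653 contigs; each point is a library and the squares are the control. Control and day 0 lie on the left, day 3 stands alone at the top with scores of 99.0 and 111 on the second component, and days 6 to 12 lie on the right.

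More contigs were measured in the later libraries. Contigs below 0.01 FPKM numbered 10243 ± 108 (SD, n = 2) in the control and 10897 ± 636 (SD, n = 2) on day 0. The number was 6739 ± 2651 (SD, n = 2) on day 3, 2937 ± 260 (SD, n = 2) on day 6, 1950 ± 370 (SD, n = 2) on day 9 and 1262 ± 57.3 (SD, n = 2) on day 12. A set of 8281 contigs, 26.9% of the table, lay below 0.01 FPKM in all 4 control and day 0 libraries, and 86 contigs lay below it in all 8 later libraries. These counts are not like for like, since the later condition spans more libraries and days and is the stricter. The 8281 contigs are called early-unmeasured here, and 1100 of them passed the filter for testing. They made up 3.83% and 3.52% of the total FPKM in the day 12 libraries. On day 3 they made up 1.42% in library 1 and 0.140% in library 2. Their summed FPKM differed 11.2-fold between those libraries, and 12.8-fold over the 1100 tested members. The sum of the other tested contigs differed 1.09-fold, which is nearly fixed because they hold almost all FPKM of a library. Per contig, the median log2 ratio on log2(FPKM + 0.1) was 2.88 over the 1100 tested members and 0.0014 over the other tested contigs. The filter uses the mean of all libraries, day 3 library 1 included, which can raise the 12.8-fold and the 2.88 of the tested members. A value of 0 is reported as listed, since 10 of the 1000 contigs with the highest median also lay below 0.01 FPKM in at least 1 library. Over the 6 groups the number of contigs below 0.01 FPKM differed by more than the spread within groups. Among the 10395 ways to pair the 12 libraries, only the real groups gave so small a spread (exact permutation p = 9.62e-05, the smallest possible, a test chosen after seeing the data). Single groups of 2 were not tested against each other.

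**Figure D2:**
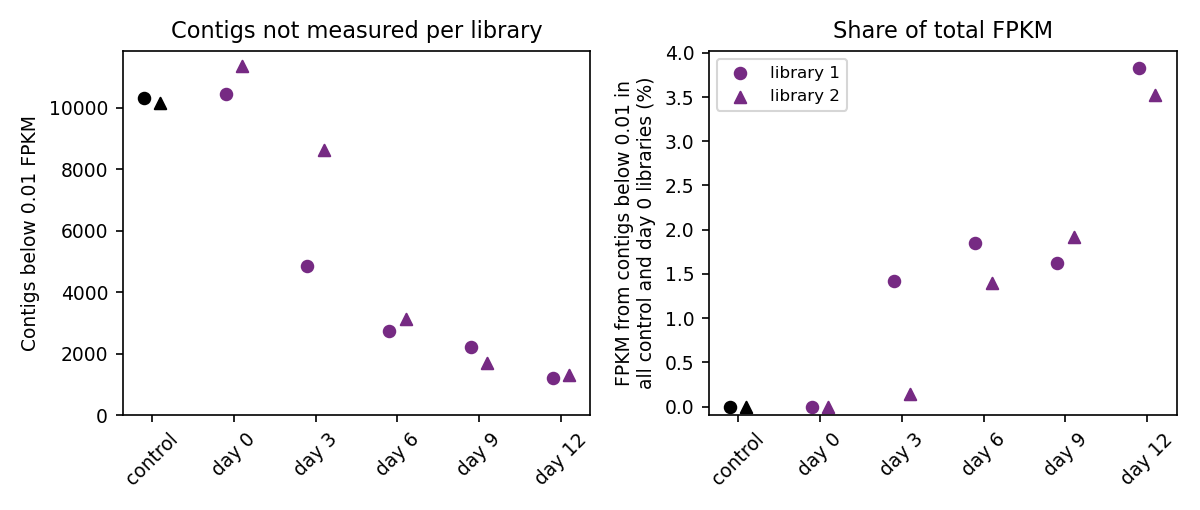
Left, number of contigs below 0.01 FPKM in each library (y axis) by group (x axis); right, percent of the total FPKM that comes from the 8281 early-unmeasured contigs, which is near 0 in control and day 0 libraries by definition of the set. Circles are library 1 and triangles library 2 of each group, black marks the control, and the day 3 libraries differ most, at 1.42% and 0.140%.

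The comparison of day 0 with the control covered the earliest treated sampling day. Since the day of the control is not certain, this difference may also hold a difference in culture age. On day 0, 1439 contigs were higher and 1864 lower than in the control, 18.7% of the 17653 tested (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05, n = 2 libraries per group). The median change was 1.63-fold among the higher contigs and 2.01-fold among the lower ones, on the log2(FPKM + 1) scale, which understates the change of low contigs. By at least 2-fold 938 contigs fell and 326 rose, 1264 of the calls. With libraries rescaled by their median ratio the balance of all calls turned, to 1531 higher and 1486 lower, while at 2-fold or more falls stayed the more frequent, 698 against 327 rises.

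The strongest rises on day 0 were short-lived in one contig and partly kept in another. TRINITY_DN15582_c0_g1_i1_3 rose from 2.24 ± 0.135 FPKM in the control to 75.3 ± 6.91 on day 0 (SD, n = 2), 33.5-fold, with a log2 change of 4.55 (SE 0.15) and a limma adjusted p of 1.50e-06. By day 3 it stood at 0.994 ± 0.118 FPKM and on days 6, 9 and 12 at 0.120, 0.176 and 0.149 FPKM, below the control in each of these contrasts, with a log2 change of -1.50 on day 12 (limma adjusted p = 2.78e-05). TRINITY_DN20388_c0_g1_i1_2 rose from 0.501 ± 0.227 to 17.6 ± 1.39 FPKM (SD, n = 2), 35.1-fold, with a log2 change of 3.63 (SE 0.35, limma adjusted p = 0.000479). It stood at 1.90 ± 0.559 FPKM on day 3 and remained above the control on day 12 at 5.61 ± 1.59 FPKM (log2 change 2.13, limma adjusted p = 0.000540), while its day 9 libraries differed, at 5.14 and 13.0 FPKM.

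The strongest falls were nearly complete on day 0 and were followed by a partial return from day 6 on. TRINITY_DN1106_c0_g1_i3_4 fell from 219 ± 34.7 FPKM in the control to 1.68 ± 0.563 on day 0 (SD, n = 2), 131-fold, with a log2 change of -6.37 (SE 0.18, limma adjusted p = 8.11e-07). Its level was 2.79 FPKM on day 3, 31.1 on day 6, 44.6 on day 9 and 63.8 ± 9.64 on day 12. TRINITY_DN16_c0_g1_i1_4 fell from 86.5 ± 16.4 to 0.890 ± 0.127 FPKM (SD, n = 2), 97.1-fold, with a log2 change of -5.52 (SE 0.16, limma adjusted p = 8.11e-07). It stood at 0.313 FPKM on day 3, 3.13 on day 6, 6.03 on day 9 and 12.6 ± 1.52 on day 12. Both contigs rose from day 3 to day 6, by 3.08 (limma adjusted p = 2.04e-06) and 1.66 (limma adjusted p = 4.25e-05) on the log2 scale. On day 12 both were still below the control, with log2 changes of -1.76 (limma adjusted p = 2.59e-05) and -2.67 (limma adjusted p = 1.10e-06).

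The number of contigs called on day 0, 3303, depended on single libraries. It was 497 without control library 1, 1213 without control library 2, 1846 without day 0 library 1 and 1452 without day 0 library 2, and 1211 when these 4 libraries were fitted alone.

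By day 3 most of the tested contigs differed from the control. Of the tested contigs 63.9% were called, with 3654 higher and 7621 lower. The median change was 2.29-fold among the higher contigs and 2.79-fold among the lower ones, and 7864 of the 11275 calls reached 2-fold. Of the contigs called higher, 173 were early-unmeasured, the set whose sum differed 11.2-fold between the day 3 libraries. The excess of lower contigs, 67.6% of the calls, held for FPKM as deposited. After the rescaling, 5648 contigs were higher and 5470 lower, 49.2% of the calls, and the median change of all contigs against the control moved from -0.37 to 0.08 on the log2 scale, a shift of 0.45.

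On days 6, 9 and 12 the difference from the control was about as wide as on day 3, with a larger median rise. Day 6 had 5393 contigs higher and 6796 lower, day 9 had 5564 and 6464, and day 12 had 5888 and 6677. These calls covered 69.0%, 68.1% and 71.2% of the tested contigs. The median rise among the contigs called higher was 2.55-fold on day 6, 2.69-fold on day 9 and 3.16-fold on day 12, against 2.29-fold on day 3, while the median fall was 2.48-fold, 2.43-fold and 2.50-fold. These medians belong to different lists of contigs and were not tested against each other. Early-unmeasured contigs were 866 of those called higher on day 6, 901 on day 9 and 967 on day 12, which is 16.1%, 16.2% and 16.4%. With rescaled libraries the split turned from more lower to more higher contigs on all 3 days, with 6403 higher and 5273 lower on day 6, 6372 and 5255 on day 9, and 6855 and 5364 on day 12. Rescaling shifted the median of all contigs by 0.28, 0.24 and 0.27 on the log2 scale. Without the low-value filter and without rescaling the split turned too, with 7903 higher and 7709 lower on day 6, 8863 and 7217 on day 9, and 12488 and 7485 on day 12.

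**Figure D3:**
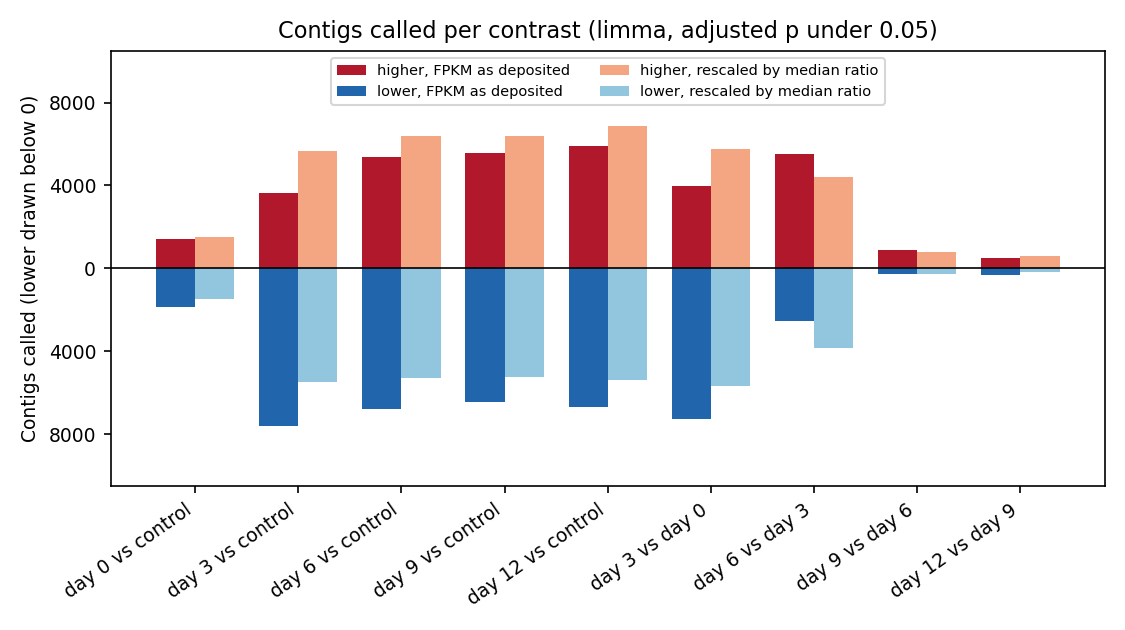
Number of contigs called higher (red, above 0) and lower (blue, drawn below 0) in each of the 9 contrasts (x axis) at a limma adjusted p under 0.05, for FPKM as deposited (dark) and for libraries rescaled by their median ratio (light). The contrasts with the control from day 3 on and day 3 against day 0 each hold 11222 to 12565 calls, day 9 against day 6 and day 12 against day 9 hold 1157 and 844, and rescaling changes the balance of higher and lower calls more than their number.

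A large group of contigs stayed away from the control from day 3 to day 12. Of the tested contigs, 4732 (26.8%) were lower than the control on days 3, 6, 9 and 12. Their median level was 9.91 and 9.99 FPKM in the control libraries and 11.0 and 11.1 FPKM on day 0, then 1.80 and 1.78 FPKM on day 3 and 2.33 and 2.40 FPKM on day 12. Another 2290 (13.0%) were higher on all 4 days, with a median of 2.92 and 2.90 FPKM in the control and 17.4 and 17.2 FPKM on day 12. In the day 3 libraries the median of the latter contigs was 16.4 and 10.4 FPKM. The 2175 that were measured early had 17.8 and 12.1 FPKM, with a median log2 ratio of library 1 to library 2 per contig of 0.022. Of them, 11.1% were over 2-fold higher in library 1 and 0.506% in library 2, so larger differences mostly favoured library 1. The 115 early-unmeasured ones had 4.10 and 0.753 FPKM, with a median log2 ratio of 2.73. If the lists of the 4 days were independent, 406 contigs would be lower and 117 higher on all of them. The 4 contrasts use the same control libraries, which are too few to be split, so part of the excess may come from them. With rescaled libraries 3255 contigs were lower and 3289 higher on all 4 days, where independent lists would share 148 and 287, so neither direction was the more frequent under both scalings, and 3255 and 2277 of the contigs were in the set under both.

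The contrast of day 3 with day 0 and that of day 6 with day 3 followed the treated cultures without the control. From day 0 to day 3, 3965 contigs rose and 7257 fell, with a median rise of 2.40-fold and a median fall of 2.95-fold. From day 3 to day 6 the balance was the opposite, with 5513 contigs rising by a median of 2.18-fold and 2535 falling by a median of 1.80-fold. Rescaled libraries gave 5747 rising and 5669 falling from day 0 to day 3, and 4407 rising and 3842 falling from day 3 to day 6, so the share of falling contigs moved from 64.7% to 49.7% and from 31.5% to 46.6%. Of the contigs rising from day 3 to day 6, 513 were early-unmeasured, as were 13 of the falling ones.

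Many contigs had a trough on day 3. In all, 3104 contigs (17.6% of those tested) fell from day 0 to day 3 and rose again by day 6. None of them was early-unmeasured, which the definition of that set fixes, since its contigs are near 0 on day 0. Their median level was 10.2 and 10.1 FPKM in the control, 11.0 in each day 0 library, 1.78 in each day 3 library, 6.23 and 6.26 on day 6 and 5.41 and 5.59 on day 12. On day 12, 1832 of them were lower than the control, 540 were higher and 732 were not called. The 540 that ended higher went from a median of 6.95 and 6.78 FPKM in the control through 2.27 and 2.62 on day 3 to 16.7 and 16.5 on day 12. The opposite course, a rise to day 3 and a fall to day 6, was taken by 1081 contigs, whose median was 10.9 and 9.38 FPKM on day 0, 27.0 and 25.8 on day 3 and 13.6 and 13.7 on day 6. Independent lists would share 2266 and 569 contigs. With rescaled libraries 2174 contigs had the trough and 2317 the peak, where independent lists would share 1415 and 1251. Of these, 2171 and 1081 were the same contigs as with FPKM as deposited, so which course was the more frequent depended on the scaling.

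**Figure D4:**
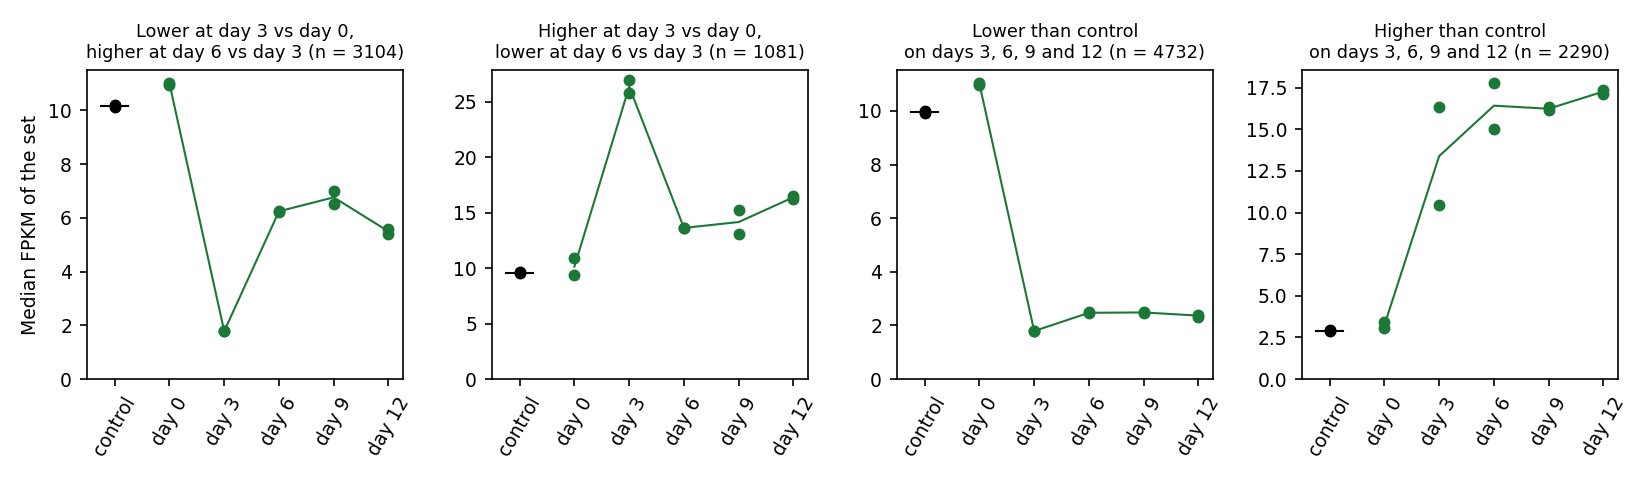
Median FPKM (y axis, linear, from 0, with a separate range per panel) of 4 sets of contigs in each library by group (x axis); points are libraries, the line joins the means of the treated days, and the horizontal bar is the mean of the control libraries. From left to right the sets are the 3104 contigs with a trough on day 3, the 1081 with a peak on day 3, the 4732 lower and the 2290 higher than the control on days 3, 6, 9 and 12; the last set differs between the day 3 libraries, at 16.4 and 10.4 FPKM.

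After day 6 fewer contigs were called from one sampling day to the next. At an unadjusted limma p under 0.05 the successive steps had 11904 contigs from day 0 to day 3, 9227 to day 6, 4333 to day 9 and 4054 to day 12, where chance would give 883. From day 6 to day 9, 892 contigs rose and 265 fell, 6.55% of those tested, with a median rise on the log2 scale of 0.95 and a median change of -0.62 among those that fell. The total of 1157 was 244 without day 6 library 1, 255 without day 6 library 2, 2856 without day 9 library 1 and 546 without day 9 library 2. In a fit of these 4 libraries alone limma called 0 contigs, with 3138 at an unadjusted p under 0.05. Early-unmeasured contigs were 74 of the 892 rising and 26 of the 265 falling contigs.

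From day 9 to day 12, 502 contigs rose and 342 fell, 4.78% of those tested, and 132 of the rising contigs and 1 of the falling ones were early-unmeasured. The total of 844 fell strongly without day 9 library 1 and without either day 12 library. It rose strongly without day 9 library 2 and without day 3 library 1. Day 3 library 1 belongs to neither group of this contrast, but it enters through the shared estimate of the spread and through the low-value filter. Without it the median log2 change of all tested contigs moved from 0.00991 to 0.00982, so the tested contigs were not the same. A fit of the 4 libraries of days 9 and 12 alone called 0 contigs with limma, with 2959 at an unadjusted p under 0.05. With rescaled libraries 597 contigs rose and 157 fell, so the share of falling contigs went from 40.5% to 20.8%. A minimum mean of 5 FPKM turned the balance, to 336 rising and 439 falling. The split was 1631 rising and 455 falling without a low-value filter, 178 and 173 with a pseudocount of 0.1, and 302 and 141 with the replicate number as a block.

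Over the whole treated course, 14828 of the 17653 contigs (84.0%) differed between the 5 sampling days (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05), 947 of them early-unmeasured. The highest mean log2(FPKM + 1) of these contigs was on day 0 for 6364 (42.9%), on day 3 for 1851 (12.5%), on day 6 for 1486 (10.0%), on day 9 for 1402 (9.46%) and on day 12 for 3725 (25.1%). The lowest was on day 0 for 5197 contigs, on day 3 for 4956, on day 6 for 1306, on day 9 for 1311 and on day 12 for 2058. Early-unmeasured contigs are low on day 0 by definition, and without them the lowest mean was on day 0 for 4250 contigs and on day 3 for 4956. With rescaled libraries 5374 contigs were highest on day 0, 3036 on day 3 and 3734 on day 12, and 5969 were lowest on day 0 and 3783 on day 3, early-unmeasured contigs included. The day of the highest mean is a description and was not tested for single contigs.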

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

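The tests with day 3 libraries divided between contrasts and of the share of abundant contigs were chosen after the result was seen, and the rescaling was planned before. In 4 comparisons the change against the control was tested for a difference between sampling days. The control cancels in this test, so the counts are those of the successive-day contrasts given above and are no further evidence. They hold exposure and the age of the culture together. The change against the control differed between days 0 and 3 in 11222 contigs and between days 3 and 6 in 8048. Between days 6 and 9 it differed in 1157 contigs (244 and 255 without day 6 libraries 1 and 2, 2856 and 546 without day 9 libraries 1 and 2). Between days 9 and 12 it differed in 844 contigs (298 and 2257 without day 9 libraries 1 and 2, 44 and 21 without day 12 libraries 1 and 2, 1715 without day 3 library 1).

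The trough of 3104 contigs on day 3 rests on contrasts that share the day 3 libraries, so a low draw of these libraries would make a fall and a rise together. With day 3 library 1 set against day 0 and library 2 against day 6, so that the contrasts shared no library, 2687 contigs had the trough. With the libraries exchanged 2525 had it, and 2593 and 2486 of these contigs were among the 3104. Independent lists would share 2116 and 1866. The contrasts still shared 1 estimate of the spread per contig, which can also raise the overlap above that of independent lists. The excess therefore does not decide whether shared libraries made part of the set. A deviation common to the day 3 libraries was not tested by this. A response to PMS that was past its lowest point by day 6 and a passing stage of culture growth both stay open as untested hypotheses, since no control of days 3 to 12 was analysed here. After rescaling 2174 contigs had the trough, 2171 of them among the 3104.

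The surplus of lower contigs on day 3 against the control, 67.6% of the calls, may come from how the libraries are scaled. The median ratio rescaling brought the share to 49.2%. That rescaling centres the ratios, so it brings the share near balance whatever the source and would also remove a real surplus of falls. The 10 most abundant contigs of each library took 14.8% ± 0.557 of the FPKM in the control and 20.3% ± 0.141 on day 3 (SD, n = 2), which lowers all others by a log2 change of -0.095. The 1000 most abundant took 73.0% ± 0.853 and 78.4% ± 0.732, a log2 change of the rest of -0.33. These changes of the rest are on plain FPKM, where the rescaling factors were 0.790 and 0.832 on day 3 and 1.30 and 1.26 in the control. The shift of 0.45 is on log2(FPKM + 1), which understates low contigs, so neither -0.095 nor -0.33 can be read as a fraction of 0.45. The factors of day 3 and the control lie much further apart than a log2 change of -0.095. That argues against a few abundant contigs as the whole source of the shift. A broad move of transcripts towards abundant contigs stays open. It cannot be told apart from library scaling since FPKM holds no outside standard.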

How the results depend on the processing

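The 4 named contigs kept direction and call in all 13 alternatives run for each, with adjusted p up to 0.0325. The number of contigs called moved by more than 1.5 times as follows, and only the smaller number of contigs or libraries entering the test shows a cause; otherwise the cause was not tested. A minimum mean of 5 FPKM, which tests fewer contigs, gave 6558 on day 3, 6589 on day 6, 6630 on day 9 and 6791 on day 12 against the control, 6751 for day 3 against day 0 and 8116 in the F test. No filter gave 19973 for day 12 against the control and 2086 for day 12 against day 9. A minimum change of 2-fold left 1264 for day 0 against the control, 4167 for day 6 against day 3, 480 for day 9 against day 6 and 282 for day 12 against day 9. Fitting the compared groups alone gave 1211 for day 0 against the control and 0 with limma for day 9 against day 6 and for day 12 against day 9 (3138 and 2959 at an unadjusted p under 0.05). A pseudocount of 0.1 gave 351 for day 12 against day 9. Single libraries left out gave 497 to 3484 for day 0 against the control, 244 to 2856 for day 9 against day 6 and 21 to 2257 for day 12 against day 9, where the lone library of a group is assumed to vary like the other groups. In every other contrast with single libraries left out the number stayed within 1.5 times.

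Replicate numbers were not taken to pair the samples, since the correlation of deviations between groups was above 0.1 in 3 of 15 pairs of groups (range -0.19 to 0.41). Those 3 were the pairs among days 3, 6 and 9 (0.41, 0.25 and 0.28), so a shared factor on these days is not excluded. The replicate number as a block gave 443 calls for day 12 against day 9, the only count that it moved by more than 1.5 times. Counts of 880 for day 9 against day 6, and of 2796 for day 0 and 11218 for day 3 against the control, stayed within 1.5 times, as did the others. Without the early-unmeasured contigs, an alternative chosen after seeing the data, 3491, 11212, 11332, 11137 and 11606 contigs were called against the control on the successive sampling days from day 0. Without day 3 library 1, also chosen after seeing the data, day 12 against day 9 had 1715 calls. The alternatives for gene lists were not run because no contig has a name. Unknown depth limits what can be said of contigs under 1 FPKM.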

Other observations

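The tests of another organism's RNA and of a more advanced day 3 library, and the follow-up of the day 0 contigs, were chosen after the result was seen. Contigs that changed on day 0 kept that direction to different degrees on day 3 and day 12. Of the 1864 contigs lower on day 0, 1017 were lower on day 3, 801 on day 6, 573 on day 9 and 479 on day 12, while the number higher than the control went from 340 on day 3 to 539, 662 and 749. On day 3 independent lists would share 805 contigs lower on both days and 386 lower on day 0 and higher on day 3, and rescaled libraries gave 601 and 477, against 460 and 475. On day 12 independent lists would share 705 contigs lower on both days and 622 lower on day 0 and higher on day 12. Of the 1439 contigs higher on day 0, 445 were higher and 695 lower on day 12, against 480 and 544 for independent lists. On day 3 the higher contigs were 395 higher and 737 lower, against 298 and 621. With rescaled libraries this balance turned, to 650 higher on both days and 515 higher then lower, against 490 and 474. Shared control libraries push such overlaps towards the same direction. With rescaled libraries the numbers for day 12 were 271 lower on both days, 764 lower then higher, 563 higher on both and 623 higher then lower, where independent lists would share 452, 577, 595 and 465. Without control library 1 the number of contigs called on day 0 fell from 3303 to 497, without control library 2 to 1213 and without day 0 libraries 1 and 2 to 1846 and 1452, so these lists rest on few libraries.

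The early-unmeasured contigs grew in level over the course, and 218 of the 8281 averaged at least 5 FPKM in the later libraries and 14 at least 50 FPKM. A lower depth of the early libraries would leave about 1799 contigs below 0.01 FPKM if every contig had its day 12 level, by the rate at which control library 2 missed contigs of control library 1, and 8281 were missed by all 4. Library 1 lay nearer the late days on the first principal component. Tested contigs with an early mean (control and day 0 libraries) of at least 1 FPKM numbered 14144. Over them, libraries 1 and 2 had covered 0.795 and 0.833 of the way from the early mean to that of days 6 to 12. This share takes rising and falling contigs together, so it cannot show whether rising contigs alone lagged in library 2. Among these contigs, 552 that rose by at least 2 on the log2 scale by day 6 had a median log2 ratio of -0.16. That argues against a more advanced library 1 as the whole source, for the contigs it covers. Of the 2175 early-measured contigs higher than the control from day 3 on, 11.1% were over 2-fold higher in library 1. In library 2 it was 0.506%, so a lead of library 1 in part of the rising contigs is not excluded. Over the 3509 contigs with a lower early mean, which include the 1100 tested early-unmeasured ones, the shares were 0.744 and 0.296. RNA of another organism growing in the later cultures is a hypothesis that stays open. The median log2 ratio of the day 3 libraries, on log2(FPKM + 0.1), was 1.66 over all members, below the 2 set as its bound. It was 2.88 over the 1100 tested members (85.4% higher in library 1), above the bound, against 0.0014 for the other tested contigs. The filter uses the mean of all libraries, so a high value in day 3 library 1 helps a member pass and can raise the ratio of 2.88. The ratio over all members depends on the constant added, since the median member stood at 0.290 FPKM in library 1 and at 0 in library 2. The bound therefore cannot decide the question. Algal genes turned on together with culture age or exposure could give such ratios too, if the day 3 libraries differed in age or exposure. This stays open as untested, since neither sequences nor annotation were used here.

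The appended number of the contig IDs went with this set. Early-unmeasured contigs were 3023 of 8302 (36.4%) with the number 2 and 3352 of 10596 (31.6%) with the number 4, against 863 of 5193 (16.6%) with 1 and 1043 of 6723 (15.5%) with 3. What the number stands for is not given in the sources used here.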
